A study of Rattus norvegicus with 6 samples.

How the data were processed

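Poly(A)-selected RNA of 6 pooled groups (3 animals each) was made into Ion Total RNA-Seq libraries and read on an Ion Torrent Proton sequencer, per the labels' protocols. The deposited files hold raw read counts per Ensembl gene ID, 1 file per library, followed by summary lines of the counting program. TopHat2 2.0.13 and HTSeq 0.6.1 are named in the submitters' processing notes. The genome build, annotation release and strand setting are not given in the sources used here, so reads of overlapping, antisense and near-identical genes could be split or lost, and this cannot be judged per gene.

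The summary lines name no gene and were left out of library sizes and tests. Reads outside annotated genes made up 7.66%, 7.00% and 7.52% of uniquely aligned reads in liver control, IR and treated IR, and 6.23%, 8.34% and 7.57% in the hepatocyte libraries in the same order. Ambiguous reads made up 0.369% to 0.798%. Reads in genes per library ran from 1945331 to 7160610, so that 3 reads, the limit taken for a count of 0, equal from 0.40 TMM-scaled CPM in liver treated IR to 1.39 in hepatocyte treated IR. Counting intervals and floors cover counting error only, since reads carry no molecular identifiers.

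Groups were taken from the sample titles. Genes were filtered with edgeR's filterByExpr (minimum count 10, by condition), which kept 9932 genes holding 99.6% to 99.9% of reads, and libraries were scaled by TMM (factors 1.18, 0.945 and 1.24 in liver control, IR and treated IR, and 0.936, 0.971 and 0.794 in hepatocytes). Pairs of libraries were compared by TMM-scaled ratios with a 95% Clopper-Pearson interval for counting error, and a gene was called apart by a rule of size: at least 2-fold, with an interval excluding equality. No p-value was computed for a pair. Log2 ratios used a prior count of 2. The number of genes apart was set beside that between 100 simulated unchanged pairs, drawn from a negative binomial distribution at the spread of the fit across preparations and, as an addition after the data were seen, at the spread within each preparation. The latter spread is estimated from the untreated and treated IR libraries of that preparation taken as alike.

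Condition effects shared by both preparations, and hepatocytes vs liver, were tested with edgeR's quasi-likelihood test on the raw counts of all 6 libraries in an additive model of preparation and condition (2 residual degrees of freedom, common biological coefficient of variation 0.288), with Benjamini-Hochberg adjustment at 0.05. The spread in this model includes any response that differs between preparations. The labels put additional animals behind the hepatocytes, so the 2 pools of a condition were taken as separate. Correlations across genes were bootstrapped over genes (1000 draws), and lists of genes were set beside 10000 random lists matched on mean expression in 20 bins. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

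The scripts were tested on simulated data with 200 genes changed by known folds. For hepatocytes vs liver, 15 of 67 genes changed 2-fold, 47 of 67 changed 4-fold and 62 of 66 changed 8-fold were recovered, with 8 false calls among 9932 genes. For IR vs control across preparations there were 9 false calls. In a separate run on unchanged libraries, with counting error as the only variation, the counting intervals held the true ratio of 1 for 96.2% of genes. That run did not test them on changed genes or on variation between pools.

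The alternatives were DESeq2's size factors, library totals alone, no expression filter, a minimum count of 50, thinning to 1945331 reads, DESeq2's Wald test, limma-voom, a lower prior count of 0.5, a 4-fold rule and leaving out each library. Tests, samples and these alternatives were set before the data were examined. The fits of any IR vs control and the restriction to the 1987 most highly expressed genes were added afterwards. Any IR means the untreated and treated IR libraries of a preparation taken as alike.

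Before the data were examined, 33 gene lists and a rule for named genes were fixed. That rule takes the genes with the largest ratios that hold in both preparations or in all 3 conditions, the genes with the largest ratios within a preparation, members of the lists and 8 genes by symbol, and admits only genes with a symbol. Because 0 of 26689 IDs matched a symbol, it named no gene, and the lists and their set tests were not run. The 4 IDs printed were chosen after their values were seen. Of these, 3 follow the ranking of that rule among genes called between hepatocytes and liver, and the fourth is the gene DESeq2 called for treated vs untreated IR. The ranking by IR vs control was also looked at. Its first 4 genes had 0 to 43 reads per library and adjusted p-values of at least 0.996, and were set aside for that reason.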

Results

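RNA was sequenced from rat liver (Rattus norvegicus) after ischemia reperfusion (IR), in which blood flow to the liver is stopped by clamping the portal vein and then restored. The series asks whether interfering with vasoconstriction or with inflammation improves the outcome of this injury. Livers came from healthy untreated animals (control), from animals with IR alone, and from animals with IR that received etanercept and nitroglycerin (treated IR). Etanercept, a receptor fusion protein that binds tumor necrosis factor, was given at 9 mg/kg between 18 and 16 h before IR. Nitroglycerin, a nitric oxide donor, was infused at 6 µg/kg/min before and during IR. Each of the 3 conditions was measured in whole liver and in hepatocytes freshly isolated by collagenase perfusion from additional animals, with RNA taken 1 day after IR. RNA of 3 animals was pooled for each library, so the 6 groups hold 1 library each. A difference between 2 libraries therefore has no replicate check, and higher and lower below describe those libraries. The animals called control were healthy, and the labels name no sham operation, so IR vs control also compares operated with unoperated animals.

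The libraries differed in depth. Reads counted in genes numbered 1945331 in liver control, 7160610 in liver IR and 6059666 in liver treated IR. In hepatocytes they numbered 3448652 in control, 5335184 in IR and 2716994 in treated IR. Of 26689 gene IDs, 16548 had a read in at least 1 library and 9932 passed the expression filter. Thinned to 1945331 reads, the liver libraries detected 12729, 12670 and 13108 gene IDs (control, IR, treated IR), and the hepatocyte libraries 11252, 11463 and 11111. One and the same gene was the most abundant in all 6 libraries. It took 14.9% of reads in liver control (95% Wilson interval 14.8 to 14.9), 13.8% in liver IR (13.7 to 13.8) and 8.76% in liver treated IR (8.73 to 8.78). In hepatocytes it took 10.2% in control (10.1 to 10.2), 19.4% in IR (19.4 to 19.4) and 8.10% in treated IR (8.06 to 8.13). The intervals cover counting error only. The files name genes by Ensembl ID and do not pair the IDs with symbols, and 0 of 26689 IDs matched the reference table, so genes are described as groups by their behaviour.

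Hepatocytes were compared with whole liver to show which transcripts differed between the preparations. The hepatocytes came from additional animals, and the cause of a difference was not tested. Of 9932 genes, 487 were lower and 43 higher in hepatocytes than in liver (edgeR quasi-likelihood test with condition as a term, 3 libraries per preparation, adjusted p at most 0.05). The lower genes had a median log2 ratio of -3.64 (interquartile range -4.48 to -2.96), and 359 of them were at least 8-fold lower. The higher genes had a median of 2.01 (1.35 to 2.86), and 10 were at least 8-fold higher. The direction was the same in all 3 conditions for 486 of the 487 lower genes and for 43 of the 43 higher genes. The test that picked these genes used the same libraries, so this is no independent check. ENSRNOG00000008015 was higher in hepatocytes, at 23.4 ± 13.1 CPM against 0.366 ± 0.405 CPM in liver (SD across the 3 conditions, n = 3), with 208 against 8 reads. In hepatocytes it was at 29.8 CPM in control, 8.31 in IR and 32.0 in treated IR. Its log2 ratio was 5.48 (SE 0.50, edgeR adjusted p = 2.35e-05). ENSRNOG00000019661 was also higher, at 47.6 ± 7.47 against 2.13 ± 1.25 CPM (SD across the 3 conditions, n = 3) and a log2 ratio of 4.67 (SE 0.39, edgeR adjusted p = 1.36e-05). ENSRNOG00000047321 was lower, with 3 reads in all hepatocyte libraries against 2316 in liver. The liver level was 493-fold higher (95% Clopper-Pearson counting interval 168 to 2390, edgeR adjusted p = 9.81e-07). The ranking that gave these genes takes only genes with the same direction in all 3 conditions. Without the liver IR library 160 genes were called higher, and without the hepatocyte IR library 154. Scaling by library total alone called 24 genes higher, and a minimum count of 50 called 28 higher and 130 lower.

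**Figure D1:**
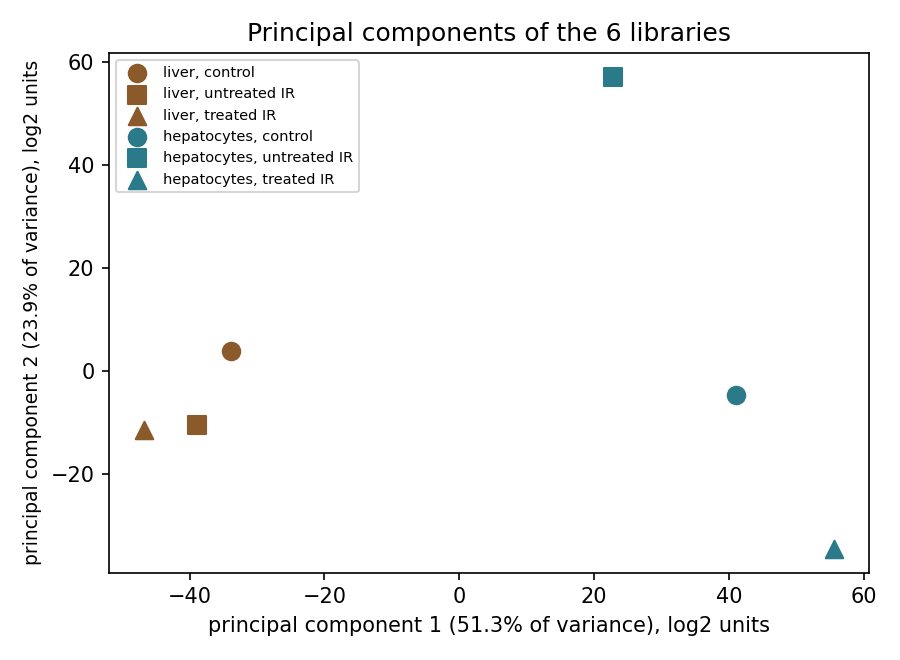
Principal components of the log2 expression of 9932 genes, with 1 point per pooled library, component 1 on the x axis (51.3% of the variance) and component 2 on the y axis (23.9%). Component 1 separates the 3 liver libraries from the 3 hepatocyte libraries. On component 2 the untreated IR hepatocyte library lies at 57.2, control hepatocytes at -4.65 and treated IR hepatocytes at -34.5.

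IR was compared with control in whole liver. By the rule of size, a ratio of at least 2-fold with a counting interval that excludes equality, 373 genes were higher and 221 lower in the IR library, 594 in all. Simulated pairs of unchanged libraries had a median of 1199 such genes (at most 1279) at the spread of the fit across preparations. At the spread between the 2 liver libraries after IR they had a median of 279 (at most 320). The split depended on scaling: with library totals alone, all log2 ratios shifted by -0.32, and 132 genes were higher and 575 lower, which is 18.7% higher in place of 62.8%. A minimum count of 50 left 155 higher and 99 lower.

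In hepatocytes the same comparison gave 947 genes higher and 688 lower after IR, 1635 in all. The simulated unchanged pairs had a median of 1212 (at most 1292) at the spread of the fit across preparations and of 2489.5 (at most 2632) at the spread between the hepatocyte libraries after IR. The number of genes apart thus lay between these levels. The higher level takes the untreated and treated IR hepatocytes as alike, so it includes any drug effect and any deviation of the IR library compared here. It is therefore not the level of unchanged hepatocyte pools. With library totals alone 1049 genes were higher and 605 lower, and with a minimum count of 50 the numbers were 528 and 351.

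Between the preparations the IR responses were weakly opposed. Across all 9932 genes the log2 ratios of IR vs control in liver and in hepatocytes had a Pearson r of -0.098 (bootstrap interval over genes -0.133 to -0.067) and a Spearman rho of -0.031. This correlation is across genes, which are not independent replicates. Among the 1987 most highly expressed genes, a subset chosen after seeing the data, r was -0.356 (bootstrap interval over genes -0.425 to -0.287) and rho -0.206. In the 1987 genes of lowest expression r was -0.043. Of the genes apart in both preparations, 45 were higher in both (35.6 in independent lists) and 12 lower in both (15.3). A further 74 were higher in liver and lower in hepatocytes (25.8), and 38 were lower in liver and higher in hepatocytes (21.1).

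**Figure D2:**
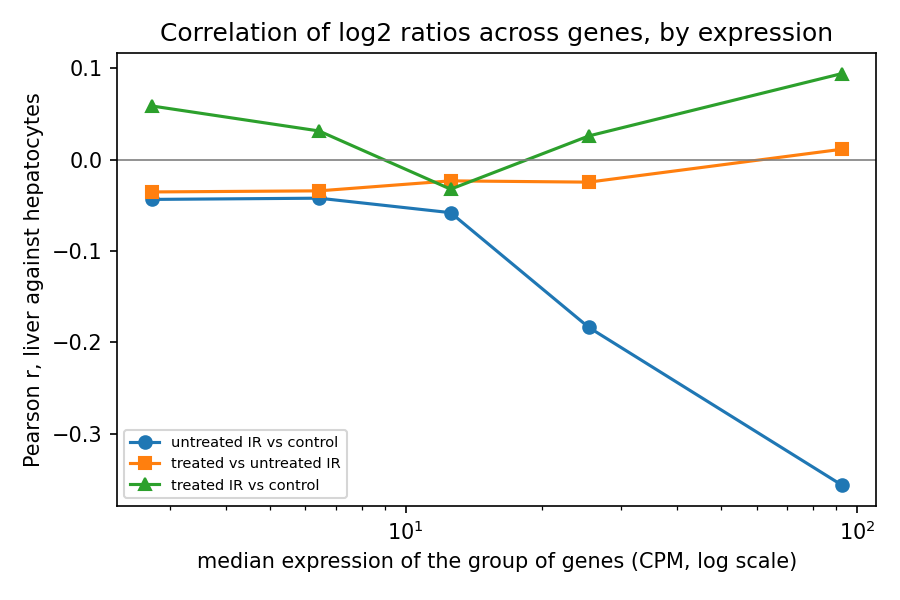
Pearson correlation across genes between the log2 ratio in liver and that in hepatocytes (y axis) against the median expression in CPM of 5 groups of genes ordered by expression (x axis, log scale), with 1 line for each of the 3 comparisons. The correlation of IR vs control goes from -0.043 in the lowest group to -0.356 in the highest, and that of treated IR vs control reaches 0.094.

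Changes shared by both preparations were tested with edgeR's quasi-likelihood test on all 6 libraries, with preparation as a term and 2 residual degrees of freedom. For IR vs control, 0 of 9932 genes passed an adjusted p of 0.05, and 332 had an unadjusted p under 0.05 where 496.6 would be expected by chance. DESeq2 and limma-voom also called 0 genes, with 119 and 300 at an unadjusted p under 0.05. On simulated data this comparison recovered 2 of 67 genes changed 2-fold, 48 of 67 changed 4-fold and 57 of 66 changed 8-fold. Those data were drawn independently per library, with the same fold in both preparations. The real fit gave fewer small p-values than expected by chance, so the test was cautious here and its recovery may be lower. Without the liver IR library, when the hepatocyte library alone stood for IR, 357 genes were called. Leaving out liver control, liver treated IR, hepatocyte control, hepatocyte IR or hepatocyte treated IR gave 3, 3, 1, 22 and 3 genes. With no expression filter 3 genes were called.

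Treated IR was compared with IR alone to ask what the 2 drugs changed. In liver, 181 genes were higher and 94 lower in the treated library, 275 in all, beside simulated medians of 1229.5 (at most 1300) at the spread of the fit across preparations and 219.5 (at most 261) at the spread within liver, which was estimated from these same libraries. With library totals alone all log2 ratios shifted by 0.39, and 613 genes were higher and 26 lower (95.9% in place of 65.8% higher). A minimum count of 50 left 34 higher and 24 lower, and no filter gave 332 and 172. In hepatocytes, 1113 genes were higher and 1198 lower in the treated library, 2311 in all, beside simulated medians of 1185.5 (at most 1272) and 2408 (at most 2500). The spread behind the 2408 was also estimated from these same libraries, taken as alike. Any drug effect is part of that spread, so 2311 beside 2408 cannot show whether treatment had an effect. With library totals alone the shift was -0.29, and 647 were higher and 1921 lower (25.2% in place of 48.2%). A minimum count of 50 left 652 higher and 761 lower. Across genes the treated vs untreated log2 ratios in liver and hepatocytes had r = -0.052 and rho = -0.035.

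Across both preparations edgeR called 0 of 9932 genes for treated IR vs IR alone, with 297 at an unadjusted p under 0.05, and limma-voom 0, with 299. DESeq2 called 1 gene, with 175 at an unadjusted p under 0.05. That gene, ENSRNOG00000027784, singled out after its values were seen, was at 112 CPM in liver IR and 27.5 CPM in liver treated IR (757 and 206 reads). In hepatocytes it was at 232 CPM in IR and 44.1 CPM in treated IR (1199 and 95 reads). The control libraries were at 127 CPM in liver and 87.8 CPM in hepatocytes. The log2 ratio of treated to untreated IR was -2.25 by DESeq2 (adjusted p = 0.0125), lower in 2 of 2 preparations. By edgeR it was -2.24 (SE 0.43, adjusted p = 0.856), and by limma-voom the adjusted p was 0.793. Without the liver IR library edgeR called 608 genes for this comparison and without liver treated IR 102, when hepatocytes alone stood for 1 of the conditions. Without hepatocyte IR it called 15 and without hepatocyte treated IR 12, and 0 without either control. With no expression filter 31 genes were called.

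Genes apart after IR in one preparation were then read in the other, which shares no library with the first. A percentile among random lists describes these libraries and is not a p-value, since genes do not vary independently. The 373 genes higher in liver after IR had a median treated vs untreated log2 ratio of 0.057 in hepatocytes (percentile 99.9 of 10000 random lists matched on expression, whose central range was -0.22 to 0). The 221 genes lower in liver after IR had a median of -0.42 in hepatocytes (percentile 0, range -0.21 to 0.085). In the other direction, the 947 genes higher in hepatocytes after IR had a median of -0.029 in liver (percentile 0.28, range -0.017 to 0.030). The 688 genes lower in hepatocytes had a median of -0.038 (percentile 2.76, range -0.038 to 0.012). The same lists were also read in IR vs control of the other preparation, a ratio that shares the untreated IR library with the treated vs untreated one. There the 373 and 221 genes from liver had medians of -0.019 (percentile 1.87) and 0.31 (percentile 100) in hepatocytes, and the 947 and 688 genes from hepatocytes had medians of 0.068 (percentile 78.35) and 0.18 (percentile 100) in liver. With genes at least 4-fold apart the treated vs untreated medians were 0.42, -1.06, -0.12 and -0.16, in the same order.

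Treated IR was compared with control to ask how far treated animals stood from healthy ones. In liver 478 genes were higher and 237 lower, 715 in all, beside simulated medians of 1193.5 (at most 1286) and 273.5 (at most 305). A minimum count of 50 left 171 and 121. In hepatocytes 420 were higher and 406 lower, 826 in all, beside simulated medians of 1156.5 (at most 1246) and 2327.5 (at most 2446). With library totals alone 187 hepatocyte genes were higher and 811 lower (18.7% in place of 50.8%), with a shift of -0.24, and a minimum count of 50 left 221 and 247. Across both preparations edgeR called 0 genes (230 at an unadjusted p under 0.05), DESeq2 0 (101) and limma-voom 0 (225). With no filter edgeR called 14. Leaving out liver IR, liver treated IR, hepatocyte control, hepatocyte IR or hepatocyte treated IR gave 26, 21, 19, 34 and 17 genes.

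**Figure D3:**
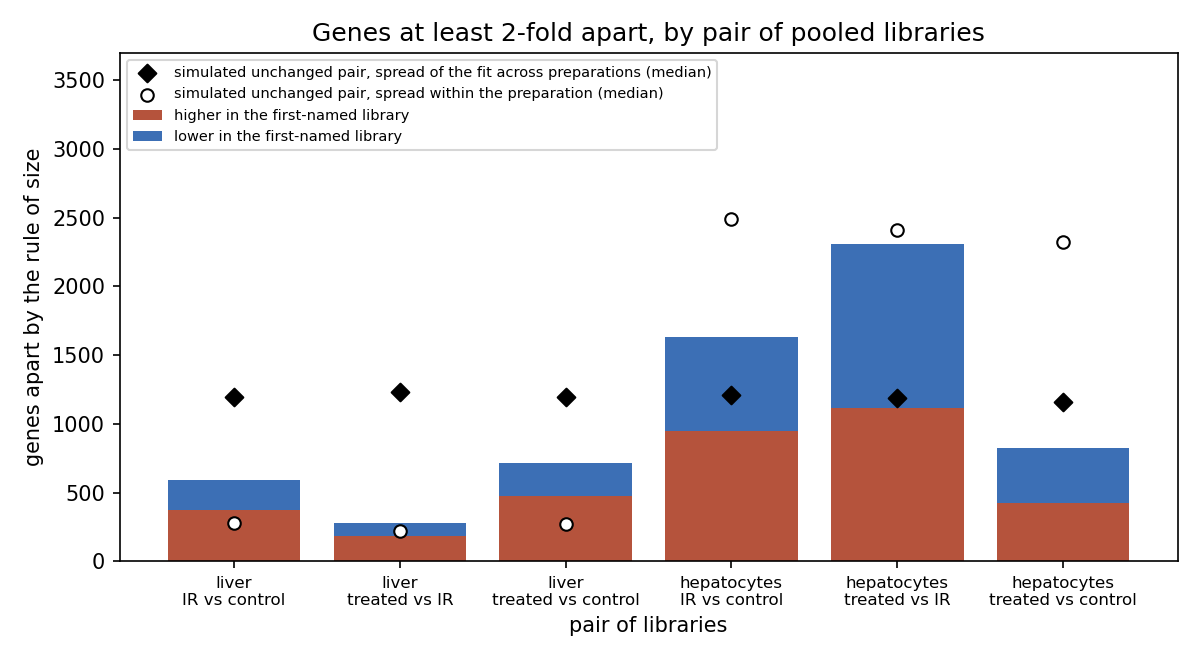
Number of genes apart by the rule of size (y axis) for the 6 pairs of pooled libraries (x axis), split into genes higher and lower in the first-named library, with the median of 100 simulated unchanged pairs at each of 2 estimates of the spread. The pair of treated and untreated IR hepatocytes has 2311 genes apart, and the pair of treated and untreated IR livers 275.

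The distances between libraries within each preparation were ordered differently. In liver the root-mean-square log2 distance over 9932 genes was 0.592 between control and IR, 0.628 between control and treated IR, and 0.388 between IR and treated IR. Thinned to 1945331 reads per library these distances were 0.592, 0.603 and 0.50. In hepatocytes it was 0.814 between control and IR, 0.699 between control and treated IR, and 0.990 between IR and treated IR, and after thinning 0.805, 0.679 and 0.947. In liver, the log2 ratios of IR and of treated IR to the shared control had r = 0.796 and a covariance of 0.290 across genes. Simulated unchanged libraries sharing that control had a median r of 0.593 and covariance of 0.293 at the spread of the fit across preparations, and 0.685 and 0.157 at the spread within liver. The observed covariance thus differed from the simulated one by -0.0031 and 0.133. With counting error as the only variation, simulated libraries sharing that control had a median r of 0.774 and covariance of 0.115. Of the genes apart, 227 were higher in both livers after IR (18.0 in independent lists) and 110 lower in both (5.27), and part of this excess may come from the shared control. In hepatocytes r was 0.151 and the covariance 0.0859, beside simulated values of 0.493 and 0.250 at the spread across preparations and 0.497 and 0.444 at the spread within hepatocytes.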

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

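The test of counting noise, both tests of the untreated IR hepatocyte library alone and the test of exchanged labels, under the first pattern, and the test of low depth under the second were chosen only after the result was seen. The fits of any IR vs control, the spread within liver and the restriction to the 1987 most highly expressed genes were added after the data were seen. The fits of any IR took the untreated and treated IR libraries of a preparation as alike, with the same spread for both preparations. Any drug effect, also one in hepatocytes alone, is part of that spread. A lack of called genes in liver therefore cannot show that IR had no effect there.

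In liver and hepatocytes 112 genes were at least 2-fold apart in opposite directions for IR vs control, and 43 for treated vs untreated IR. Of the 43, 20 were higher in liver and lower in hepatocytes (21.8 in independent lists), and 23 the reverse (10.5). For treated vs untreated IR, 13 genes were higher in both preparations (20.3 in independent lists) and 20 lower in both (11.3). For these comparisons the difference between the preparations was not tested, and a test of it for any IR vs control is given under the first pattern. Alignments that were not unique, which no comparison used, made up 60.1% of alignments in the liver IR library, against 46.3% in liver control. These are alignments and not reads, so a read placed many times counts many times.

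The first pattern is that the IR responses of liver and hepatocytes shared no direction: they were weakly opposed over all genes (r = -0.098) and more so in abundant ones. Counting noise hiding a shared response is argued against by r = -0.356 where counts are highest. The untreated IR hepatocyte library as sole cause stays open, both for the missing shared response and for the opposition in abundant genes. Treated IR vs control, which does not use that library, had r = 0.0252 (bootstrap interval 0.0018 to 0.049) over all genes. In abundant genes its r was 0.094 (bootstrap interval 0.049 to 0.142). Treated IR adds the drugs and comes from other pools, so a low r there cannot show what untreated IR would share. Exchanged labels of the control and untreated IR hepatocyte libraries may be a candidate explanation, with r = 0.357 (rho 0.201) between the preparations for treated IR vs control once exchanged in the 1987 genes and r = 0.079 over all genes, but this is no evidence of an exchange, because the idea came from distances that nearly fix that value and treated vs untreated IR then had r = -0.060. A response that differs between whole liver and isolated hepatocytes also stays open, with 0 genes past edgeR's test of the difference for any IR vs control (296 at an unadjusted p under 0.05, DESeq2 1, limma-voom 0) and preparation and pool confounded.

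The second pattern is that liver IR and liver treated IR stood apart from control alike, though at equal read number their distance to each other was 0.50 against 0.592 and 0.603 to control, less of a gap than the 0.388 against 0.592 and 0.628 at full depth. Low depth of the control library as the whole cause is argued against by the covariance of 0.236 (bootstrap interval 0.20 to 0.28) in the 1987 most highly expressed genes, against at most 0.0117 from counting noise at these depths, while a bound of 0.5 on r set beforehand was dropped because counting noise with the shared control passed it alone (0.758). Over all genes, counting noise with the shared control gave a median r of 0.774, beside 0.796 observed. Its median covariance was 0.115 (at most 0.123), so it can account for part of the observed 0.290. The shared control alone could account for the covariance of 0.290 over all genes, against a simulated median of 0.293 and maximum of 0.307 at the spread across preparations. At the spread within liver the simulated maximum was 0.167, and in the 1987 genes the observed 0.236 lay above the maximum of 0.223 at the wider spread, so the answer depends on a spread that single pools cannot settle. An unusual control pool and an effect of IR that treatment left in place cannot be told apart with 1 control pool, and any IR vs control in liver had 0 genes by edgeR (244 at an unadjusted p under 0.05, DESeq2 5, limma-voom 0).

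The third pattern is that untreated IR hepatocytes stood furthest from the other hepatocyte libraries. Treated IR hepatocytes also stood apart from control, at a distance of 0.699 (0.679 thinned). On component 2 they lay at -34.5, on the other side of control (-4.65) from untreated IR (57.2). Counting noise is argued against by a distance to control 1.45 times that of treated hepatocytes in the 1987 most highly expressed genes. More RNA of cells that isolation removes may contribute, but this stays open. The 504 genes at least 8-fold lower in hepatocytes, picked in the treated libraries, had a median IR vs control log2 ratio of 0.447 in hepatocytes. Random lists had 0.093 to 0.33, and the median fell short of the 0.5 set beforehand. The same genes had 0.39 in liver IR vs control (0.077 to 0.24). The 384 genes picked in control had -0.52 in treated vs untreated hepatocytes (-0.42 to -0.15). In each of these readings the library with more reads was the higher one, but this did not hold for every reading. In liver treated vs untreated the 384 genes had 0.13 (0.047 to 0.15), although the treated library had fewer reads. The 403 genes picked in untreated IR had 0 in treated vs control hepatocytes (0 to 0) and 0.60 in treated vs control liver (0.20 to 0.38). The upper quartile of the 504 genes in hepatocytes, 0.905, equals the ratio of 2 reads to 0, so part of that list lay near the floor. Random lists were matched on mean expression over all 6 libraries and not on hepatocyte reads. Picking genes in a library also favours deviations it shares with those read. An effect of IR that treatment lowers stays open: the median treated vs untreated ratios in hepatocytes of 0.0565 for genes higher and -0.42 for genes lower in liver after IR decide nothing, since IR vs control in hepatocytes had medians of -0.019 and 0.31 for these genes and shares the untreated IR library. No marker genes could be read, so no cell type was tested.

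For hepatocytes vs liver the real split gave 530 genes, and the highest of the other splits of the 6 libraries gave 0, so that 1 of 10 splits gave as many. The splits are too few for a share under 0.05.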

How the results depend on the processing

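The fits of any IR vs control, within liver, within hepatocytes and for their difference, and the restriction to the 1987 most highly expressed genes were chosen only after the data were seen. Where no cause is given, the cause was not tested. The labels give no replicate numbers, so no replicate pairing was fitted, and preparation or condition was a term in the fits across all 6 libraries. The gene lists, their set tests and the alternatives for named genes by symbol were not run, since no ID matched a symbol. Depth limits the liver control library, and 2-fold changes were mostly out of reach of the tests on simulated data.

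With library totals alone, genes higher and lower were 132 and 575 for liver IR vs control, 613 and 26 for liver treated vs untreated, 647 and 1921 for hepatocytes treated vs untreated, and 187 and 811 for hepatocytes treated vs control. Hepatocytes vs liver then had 24 higher, and any IR vs control 12 higher and 8 lower in liver, 3 higher in hepatocytes, and 11 and 11 for the difference.

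A minimum count of 50, which tests fewer genes, left 155 and 99 for liver IR vs control, 34 and 24 for liver treated vs untreated, 171 and 121 for liver treated vs control, and 528 and 351, 652 and 761, and 221 and 247 for the same comparisons in hepatocytes. Hepatocytes vs liver had 28 and 130, and the correlation of IR vs control between preparations was -0.194.

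With no expression filter, liver treated vs untreated had 332 higher and 172 lower. Across preparations edgeR called 3 higher for IR vs control, 11 higher and 20 lower for treated vs untreated, and 10 and 4 for treated vs control. Any IR vs control gave 31 and 13 in liver, 6 and 3 in hepatocytes, and 18 and 17 for the difference. DESeq2 called 1 gene lower for treated vs untreated (ENSRNOG00000027784, log2 -2.25), and 3 higher and 2 lower for any IR in liver and 1 higher for the difference.

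Leaving out 1 library leaves 1 residual degree of freedom, and the lone library of a condition is assumed to vary like the others. IR vs control then ranged from 0 to 210 higher and 1 to 147 lower, treated vs untreated from 0 to 337 and 0 to 271, in each case highest without liver IR. Treated vs control ranged from 0 to 23 and 0 to 11, highest without hepatocyte IR. Hepatocytes vs liver ranged from 41 to 160 higher and 382 to 598 lower. Any IR vs control ranged in liver from 1 to 44 and 1 to 70 (highest without hepatocyte IR), in hepatocytes from 0 to 557 and 0 to 485, and for the difference from 1 to 308 and 2 to 242 (both highest without hepatocyte treated IR), with no such fit where a control is left out.

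With the 4-fold rule, the medians read in the other preparation were 0.42 and -1.06 for genes higher and lower in liver, and -0.12 and -0.16 for genes higher and lower in hepatocytes. In the 1987 most highly expressed genes the correlations between preparations were -0.356 for IR vs control, 0.011 for treated vs untreated, which reversed sign, and 0.094 for treated vs control. Within a preparation they were 0.877 in liver and -0.011 in hepatocytes, which reversed sign. Of the alternatives set beforehand, 122 values stayed within the limits and 67 moved.

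Of the 530 genes called between hepatocytes and liver, 530 were shared with DESeq2's size factors, 508 with library totals, 436 with DESeq2's test and 523 with limma-voom.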

Other observations

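The comparison in this part was chosen only after the result was seen.

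In the 1987 most highly expressed genes, the difference of liver control from the mean of the other liver libraries had r = 0.391 with the same difference for untreated IR hepatocytes. With control hepatocytes it had r = -0.245 and with treated IR hepatocytes r = -0.311. Over all genes the values were 0.105, -0.039 and -0.086. The hepatocyte differences cancel out for each gene, so a positive value forces a negative one among the others. They use the same libraries as the opposed IR responses above and are no separate check of them.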
